A study of Mus musculus with 6 samples.

How the data were processed

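RNA was measured by sequencing in 6 mouse kidney libraries, 3 from control mice (Trf1+/+) and 3 from mice with both copies of Trf1 flanked by loxP sites (Trf1lox/lox, here called Terf1_flox). Trf1 is the protein name of the gene Terf1. Per the labels, all mice carried a tamoxifen-inducible Cre recombinase driven by the Ksp-cadherin (Cdh16) promoter together with a fluorescent reporter (KFP). Tamoxifen was injected 3 times a week for 8 weeks, starting in males and females of 6 to 8 weeks of age. Kidneys were digested and epithelial cells were sorted with an EpCAM antibody and the reporter signal. Whether a library holds cells of 1 mouse or of several is not given in the sources used here, so n counts libraries and the SD is that between libraries. Polyadenylated RNA was made into libraries with a kit for low cell input.

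The authors deposited a table of normalized counts, a signal in reads scaled by library, for 16095 genes named by symbol. Per the labels, DESeq2 and the mouse build GRCm39 were used; the aligner, the counting tool, the annotation and the filter that left these genes are not given in the sources used here. Every deposited value was a whole multiple of 1 step per library (within 0.01 of a read), so the whole reads behind each value were recovered by division. Size factors recomputed by the median-of-ratios method from the recovered reads matched the deposited scaling to a relative difference of 3.8e-15. The values were not divided by gene length. Reads carried no molecular identifiers used here, so any statement on depth covers counting error only. Gene coordinates are not given, because the table names genes by symbol and the reference used for transcript properties is on build GRCm38.

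The main comparison was Terf1_flox against control with limma (version 3.58.1, R 4.3.3; empirical Bayes with a mean-variance trend) on log2 of the normalized count plus 1. The 14822 genes with a mean of at least 10 over the 6 libraries were tested, with a two-sided p and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. Fold changes are Terf1_flox over control, and ± after a log2 fold change is its standard error. Group levels are means of the normalized counts ± SD (n = 3 per group). For Terf1 an exact two-sided permutation test was added; 3 libraries against 3 cannot give a p below 0.1.

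The 42 gene lists of processes, kidney and other cell types, technical signs and sex-linked genes, the tests and the alternatives were chosen before the data were examined, except where the closing section says otherwise. Of these lists, 37 had at least 3 tested members and were tested with camera (limma, preset inter-gene correlation 0.01), adjusted over the lists. The lists were also tested with an estimated correlation and with fry. Members were counted as passing when adjusted over the list alone as well as over all genes. Named genes followed a fixed rule. Terf1, Cdh16, Epcam and Cdkn1a were always named. In each direction the 12 genes with the largest fold change among those called, with a mean of at least 50 and no overlap between groups, were to be named; where fewer than 5 genes were called, the 12 with the smallest unadjusted p under the same limits took their place. Predicted and clone-named genes were left out, and from each list up to 4 members with the smallest p were eligible; other genes were named after their values were seen. Principal components used the 1000 most variable genes.

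Alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, rescaling to equal totals or upper quartiles, quantile normalization, array weights, a robust fit, a replicate block, Xist as a covariate, leaving out each library, edgeR (4.0.16) quasi-likelihood tests and DESeq2 (1.42.0) Wald tests on the recovered reads. A correction of the log2 values for transcript GC content and length, from GENCODE release 21 for mouse, was added after the data were seen. The GC content and length of a gene were medians over its annotated protein-coding transcripts, or over all its transcripts where none was protein-coding. Such a median can differ from the value of the transcript that is expressed. The tests were tried on simulated reads with the spread between these libraries and 50 genes at each size of change. limma recovered 2% of genes changed 2-fold, 20% at 4-fold, 40% at 8-fold and 56% at 16-fold, with 9 false calls among 86. edgeR recovered 2%, 20%, 34% and 52%, with 6 false calls among 70. DESeq2 recovered 8%, 36%, 54% and 68%, with 88 false calls among 195. Among 36 lists tested on the simulated reads, camera called both lists shifted by 1 log2 unit and 0 of the others. The simulated genes were drawn independently of each other, so this cannot show how often camera with the preset correlation calls unchanged lists of correlated genes. Figures were drawn with matplotlib 3.10.9.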

Results

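Gene expression was measured in sorted kidney epithelial cells of 6 libraries, 3 from control mice and 3 from Terf1_flox mice, all carrying the inducible Cre and all given tamoxifen. Terf1 encodes TRF1, a component of the shelterin complex that coats and protects telomeres. The control libraries held 16069674, 13582140 and 17680986 reads over the deposited genes, and the Terf1_flox libraries 13870931, 15375471 and 15263383 reads. Reads were found for 15106 to 15512 genes per control library and for 14845 to 15113 per Terf1_flox library. Pearson correlations of the log2 values across genes ran from 0.781 to 0.814 between control libraries, from 0.734 to 0.75 between Terf1_flox libraries and from 0.726 to 0.766 between groups; genes are not independent replicates.

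The most abundant nephron markers were those of the distal tubule. Umod, the uromodulin of the thick ascending limb, averaged 119814 ± 21723 normalized counts in control and 63592 ± 2840 in Terf1_flox libraries (SD, n = 3 each). Slc12a1, the sodium-potassium-chloride cotransporter of the same segment, averaged 36584 ± 4060 and 50653 ± 3712. Slc12a3, the thiazide-sensitive cotransporter of the distal convoluted tubule, averaged 83547 ± 31245 and 73831 ± 17404. The proximal tubule transporter Slc34a1 was far lower, between 110.5 and 287.8 in control and between 142.5 and 461.5 in Terf1_flox libraries. So was the proximal tubule marker Lrp2 (megalin), between 27.6 and 353.6 in control and between 241.2 and 964.4 in Terf1_flox libraries. Of 20 macrophage and monocyte and 9 erythroid markers, 10 and 6 reached a mean of 10 normalized counts. Of 15 endothelial, 17 fibroblast and pericyte, 15 T and NK lymphocyte, 11 B lymphocyte and plasma cell and 11 podocyte markers, 2, 1, 1, 2 and 2 reached a mean of 10, too few for a list test.

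The comparison of Terf1_flox with control cells asks what loss of TRF1 from renal epithelium does to gene expression, in a study whose title names telomere dysfunction and kidney fibrosis. Terf1 itself was 15.9-fold lower, at 560 ± 92.7 normalized counts in control and 37.3 ± 21.4 in Terf1_flox libraries (SD, n = 3 each). Its log2 fold change was −3.99 ± 0.61. The control libraries held 529.6, 486.1 and 663.9 normalized counts and the Terf1_flox libraries 62.0, 24.6 and 25.3, so the groups did not overlap. Over all genes tested, the limma adjusted p of Terf1 was 0.0814, short of the 0.05 threshold; DESeq2 gave an adjusted p of 5.42e-08, and limma on genes with a mean of at least 50 gave 0.0285. Adjusted over the list alone, among the 7 shelterin genes, Terf1 was lower with a limma adjusted p of 0.000909. The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give.

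The other 3 genes fixed in advance did not pass in limma. Cdh16, whose promoter drove the Cre, averaged 5641 ± 1354 in control and 4359 ± 365 in Terf1_flox libraries, with a log2 fold change of −0.35 ± 0.22 (limma adjusted p = 0.52); without control replicate 2 it was −0.16, with equal totals −0.52 and with equal upper quartiles −0.23. Epcam, the surface marker used for sorting, averaged 4671 ± 363 and 2081 ± 802, with no overlap and a log2 fold change of −1.23 ± 0.29 (limma adjusted p = 0.139; DESeq2 adjusted p = 0.00748). After the GC content and length correction its log2 fold change was −0.55 (limma adjusted p = 0.484). Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, averaged 616 ± 256 and 268 ± 108, with no overlap. Its log2 fold change was −1.22 ± 0.51 (limma adjusted p = 0.329, DESeq2 adjusted p = 0.199), and −0.58 after the correction.

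Across all 14822 genes, limma called 0 genes at an adjusted p below 0.05 with the deposited scaling (132 with a mean of at least 50, 45 with equal totals and 8 with quantile normalization). Here and below, limma counts over all genes use the deposited scaling and a mean of at least 10 unless stated. At an unadjusted p below 0.05 there were 2095 genes, against 741.1 expected by chance. Of these, 845 were higher and 1250 lower in Terf1_flox libraries, so 40.3% were higher. With equal library totals that share was 25.4%, and with equal upper quartiles it was 50.4%. edgeR also called 0 genes, with 1993 at an unadjusted p below 0.05, and DESeq2 called 772, of which 328 were higher and 444 lower. Of the DESeq2 calls, 736 had an unadjusted limma p below 0.05. On simulated reads, with 50 genes changed at each size and 2 lists shifted among 14059 genes, 88 of 195 DESeq2 calls were false. That share depends on how many genes truly change, so it does not give the false share of the 772 calls. The groups did not overlap for 3126 genes, 21.1% of those tested, where chance gives 10%.

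No gene was called by limma with the deposited scaling, so the genes named here are those with the smallest p in each direction. None of them passed in edgeR or in that limma fit over all genes tested. With equal totals and with quantile normalization, limma over all genes did call Eno1, Pkm, Glmp, Atp5b, Idh2, Ctsa, Ndrg2 and Tpi1. With equal totals it also called Uqcrb, Tmbim6, Ckb, Adhfe1 and Ctsb. Both limma on genes with a mean of at least 50 (lowest adjusted p 0.011, for Eno1) and DESeq2 (from 3.4e-14 for Eno1 to 0.000984 for Cox7c) called all 24. The 12 higher genes had limma adjusted p between 0.0805 and 0.0814. They included Uqcrb of complex III, at 28808 ± 3219 in control and 60450 ± 7684 in Terf1_flox libraries (log2 fold change 1.07 ± 0.15). Cox7b (1.10), Cox7c (0.88) and Cox6c (0.98) are subunits of cytochrome c oxidase, and Ndufa4 (1.06) is a further respiratory chain subunit. The ATP synthase subunits Atp5j (0.87), Atp5md (1.17) and the mitochondrially encoded mt-Atp8 (1.40) were also among them. The ribosomal protein genes Rps27 (1.34) and Rps27l (1.22), the RNA polymerase subunit Polr2k (1.36) and Rbis (1.54) were the others. Rbis averaged 2299 ± 484 and 6628 ± 801, a 2.91-fold difference.

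The 12 lower genes had limma adjusted p between 0.0742 and 0.0805. The glycolytic enzymes Eno1, Pkm and Tpi1 were among them. Eno1 averaged 10099 ± 2802 in control and 2055 ± 237 in Terf1_flox libraries, 4.81-fold lower (log2 fold change −2.27 ± 0.24). Pkm, pyruvate kinase, averaged 6678 ± 1209 and 1653 ± 224 (−2.01 ± 0.23), and Tpi1 had a log2 fold change of −1.62 ± 0.23. The cathepsins Ctsa (−2.57 ± 0.33) and Ctsb (−1.38 ± 0.20) and the lysosomal membrane protein Glmp (−2.46 ± 0.31) were also named. Ctsa, cathepsin A, averaged 2134 ± 103 and 370.3 ± 123. The mitochondrial enzymes Idh2 (−1.36) and Adhfe1 (−1.91), the ATP synthase subunit Atp5b (−1.23), the creatine kinase Ckb (−1.54), Ndrg2 (−2.02) and Tmbim6 (−1.48) were the others. These 24 log2 fold changes kept their sign under equal totals, equal upper quartiles and quantile normalization; with the last, Atp5j was at 0.51 and Cox7c at 0.52. The GC content and length correction brought many of them closer to 0. Among the higher genes, Uqcrb was then at 0.42, Rps27l at 0.58, Cox7b at 0.70, mt-Atp8 at 0.47, Polr2k at 0.60, Cox7c at 0.40, Ndufa4 at 0.44 and Rps27 at 0.80, while Atp5j was at 0.92. Among the lower genes, Atp5b was then at −0.72, Idh2 at −0.75 and Ckb at −0.82, while Eno1 was at −2.02, Pkm at −1.89 and Ctsa at −2.08. Atp5md and Rbis had no transcript values for this correction.

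**Figure D1:**
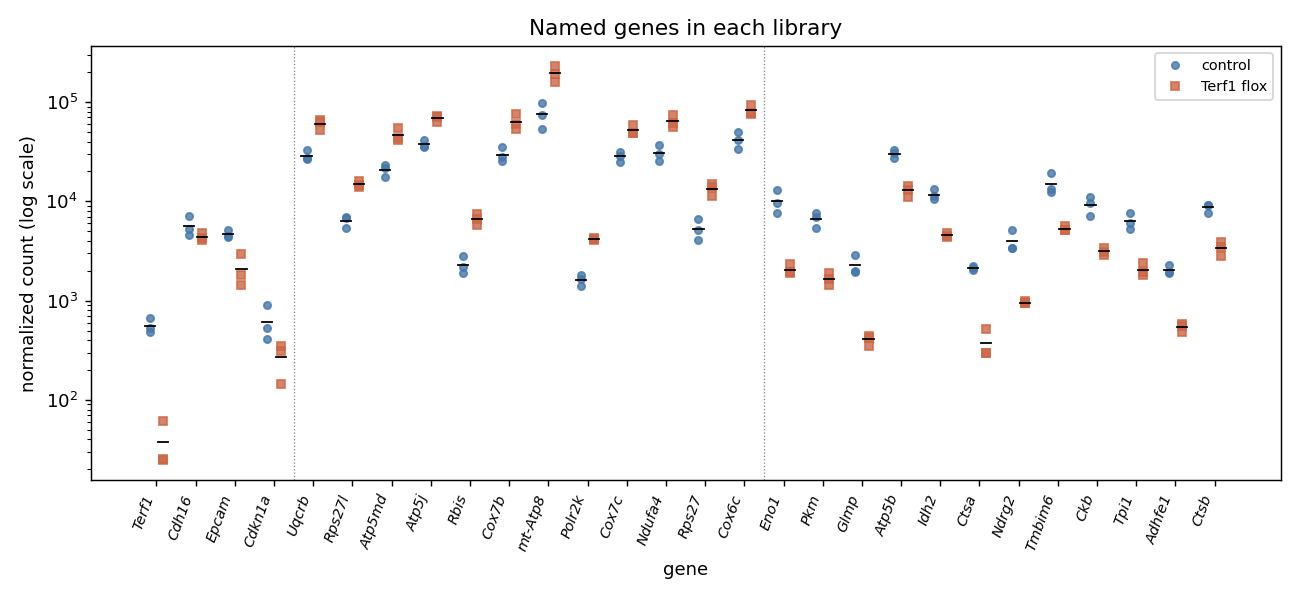
Normalized counts (log scale) of the named genes in each of the 3 control and 3 Terf1_flox libraries, with short lines at the group means. Dotted lines part the genes always named from the 12 higher and the 12 lower genes; Terf1 lay between 486.1 and 663.9 in control libraries and between 24.6 and 62.0 in Terf1_flox libraries.

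Camera called 6 of the 37 tested lists at an adjusted p below 0.05, 2 higher and 4 lower in Terf1_flox libraries. With an estimated correlation 0 lists were called, and with fry 0. The estimated correlation of the fatty acid oxidation list was 0.012, near the preset 0.01. Its adjusted p still went from 0.00474 to 0.754, so that rise does not rest on a higher correlation. The 0 calls with an estimated correlation thus cannot show whether correlation between genes accounts for the 6 calls. fry's test for change in either direction, which compares no list with other genes, called 17. Of the lists not called by camera, these were shelterin, G2/M and mitosis, apoptosis, extracellular matrix and fibrosis, TGF-beta, nuclear oxidative phosphorylation, MYC targets, oxidative stress and Nrf2 targets, Wnt, Notch and Hippo targets, thick ascending limb, dissociation and immediate early and male-enriched kidney genes. A trend with transcript GC content ran through the comparison. The median log2 fold change was 0.37 in the lowest of 5 equal GC bins (25.6% to 44.0%) and −0.49 in the highest (55.4% to 72.8%). Genes of the highest bin lay further above their mean than those of any other bin in each control library, and genes of the lowest bin did so in each Terf1_flox library.

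**Figure D2:**
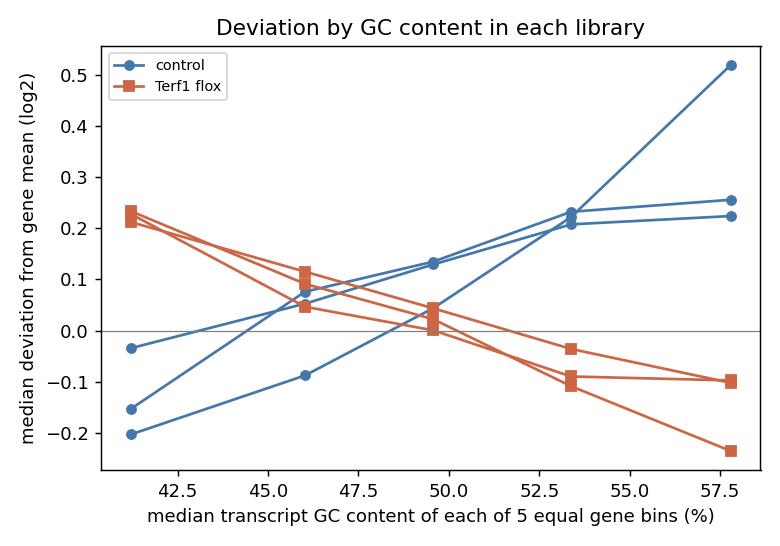
Median deviation of a gene from its mean over the 6 libraries (log2 of normalized count plus 1), in 5 equal bins of transcript GC content (%), with 1 line per library. In the highest bin the control libraries sat between 0.22 and 0.52 and the Terf1_flox libraries between −0.24 and −0.10.

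Mitochondrially encoded respiratory chain genes rose as a list (13 of 13 above 0, median log2 fold change 0.93, camera adjusted p = 6.66e-10; adjusted p = 0.754 with an estimated correlation). Over all genes 0 members passed in limma, and adjusted over the list alone 9 were higher. mt-Cytb, the cytochrome b of complex III, averaged 651552 ± 156538 in control and 1222744 ± 156795 in Terf1_flox libraries (log2 fold change 0.93 ± 0.17), and mt-Atp6 had a log2 fold change of 1.10 ± 0.23. With quantile normalization mt-Cytb was at 0.32, and with GC content and length corrected mt-Cytb was at 0.43 and mt-Atp6 at 0.32. Without control replicate 3 the list median was 0.59. The mitochondrially encoded share of all reads was 13.04%, 12.86% and 10.33% in control and 18.1%, 16.2% and 20.6% in Terf1_flox libraries. After GC content and length correction the list median was 0.20 and the list was not called (adjusted p = 0.56).

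Cytoplasmic ribosomal protein genes rose as a list (26 of 32 above 0, median 0.45, camera adjusted p = 3.51e-06; adjusted p = 0.754 with an estimated correlation). Adjusted over the list alone, 13 were higher and 3 lower, and over all genes 0 passed in limma. Rpl32 averaged 6815 ± 1230 in control and 12903 ± 1070 in Terf1_flox libraries (0.93 ± 0.19), and Rps24 had a log2 fold change of 1.19 ± 0.24 (0.72 with GC content and length corrected). Rpl3 went the other way, from 3013 ± 321 to 1277 ± 49.6 (−1.23 ± 0.23). Rpl3 did pass over all genes in limma with equal totals, and with DESeq2 (adjusted p = 0.000163). The list median was 0.27 with equal totals, and 0.53 after GC content and length correction (adjusted p = 2.67e-09).

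Glycolysis and hypoxia genes fell as a list (16 of 24 below 0, median −0.42, camera adjusted p = 0.000734; adjusted p = 0.754 with an estimated correlation). Over all genes 0 passed in limma with the deposited scaling. Eno1, Pkm and Tpi1 did pass with equal totals and with quantile normalization, and Aldoa with equal totals. Adjusted over the list alone, 7 were lower, all of them glycolytic enzymes: Eno1, Pkm, Tpi1, Aldoa, Gpi1, Pfkl and Pgam1. Aldoa averaged 21932 ± 4358 in control and 7901 ± 2157 in Terf1_flox libraries (−1.50 ± 0.25). The list median was −0.65 without control replicate 1 and −0.81 without Terf1_flox replicate 2. With GC content and length corrected, it was −0.24 (adjusted p = 0.00849).

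Unfolded protein response genes, which code for chaperones and sensors of the endoplasmic reticulum, fell as a list (18 of 22 below 0, median −0.73, camera adjusted p = 0.00459; adjusted p = 0.754 with an estimated correlation). Over all genes 0 passed in limma, and adjusted over the list alone the disulfide isomerase Pdia3 was lower (8178 ± 1849 to 3295 ± 144, log2 fold change −1.29 ± 0.21). Pdia3 did pass over all genes in limma with equal totals, and with DESeq2 (adjusted p = 1.89e-05). The chaperone Hspa5 had a log2 fold change of −1.08 ± 0.32 and Calr of −0.70 ± 0.21 (−0.29 with GC content and length corrected), neither passing in limma; with DESeq2 Hspa5 passed (adjusted p = 0.0188) and Calr did not (0.0648). Without control replicate 3 the median was −0.62 and the list was not called (adjusted p = 0.0515). Corrected for GC content and length, the median was −0.61 (adjusted p = 0.00827).

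Fatty acid oxidation genes fell as a list (22 of 29 below 0, median −0.41, camera adjusted p = 0.00474; adjusted p = 0.754 with an estimated correlation). Over all genes 0 passed in limma, and adjusted over the list alone the dehydrogenases Acadvl (−2.48 ± 0.37) and Hadh (−0.98 ± 0.24; −0.54 with GC content and length corrected) were lower. Acadvl averaged 1598 ± 502 in control and 275.0 ± 23.2 in Terf1_flox libraries. It passed over all genes in limma with equal totals, and with DESeq2 (adjusted p = 3e-08). After GC content and length correction the list median was −0.33 and the list was not called (adjusted p = 0.0906).

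Markers of intercalated cells of the collecting duct fell as a list (14 of 17 below 0, median −1.04, camera adjusted p = 0.0175, or 0.936 with an estimated correlation). Over all genes 0 passed in limma, and adjusted over the list alone the ammonia channel Rhcg was lower, at 2558 ± 241 in control and 868 ± 352 in Terf1_flox libraries (−1.63 ± 0.33). The groups overlapped: the median deviation of the markers was −0.16, 0.20 and 1.71 in control and 0.57, −0.64 and −1.15 in Terf1_flox libraries. The call was lost without control replicate 3 (median −0.44, adjusted p = 0.448), without Terf1_flox replicate 2 (−0.72, 0.0645) and without Terf1_flox replicate 3 (−0.56, 0.32). After GC content and length correction of all genes the median was −0.58 (adjusted p = 0.0673).

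**Figure D3:**
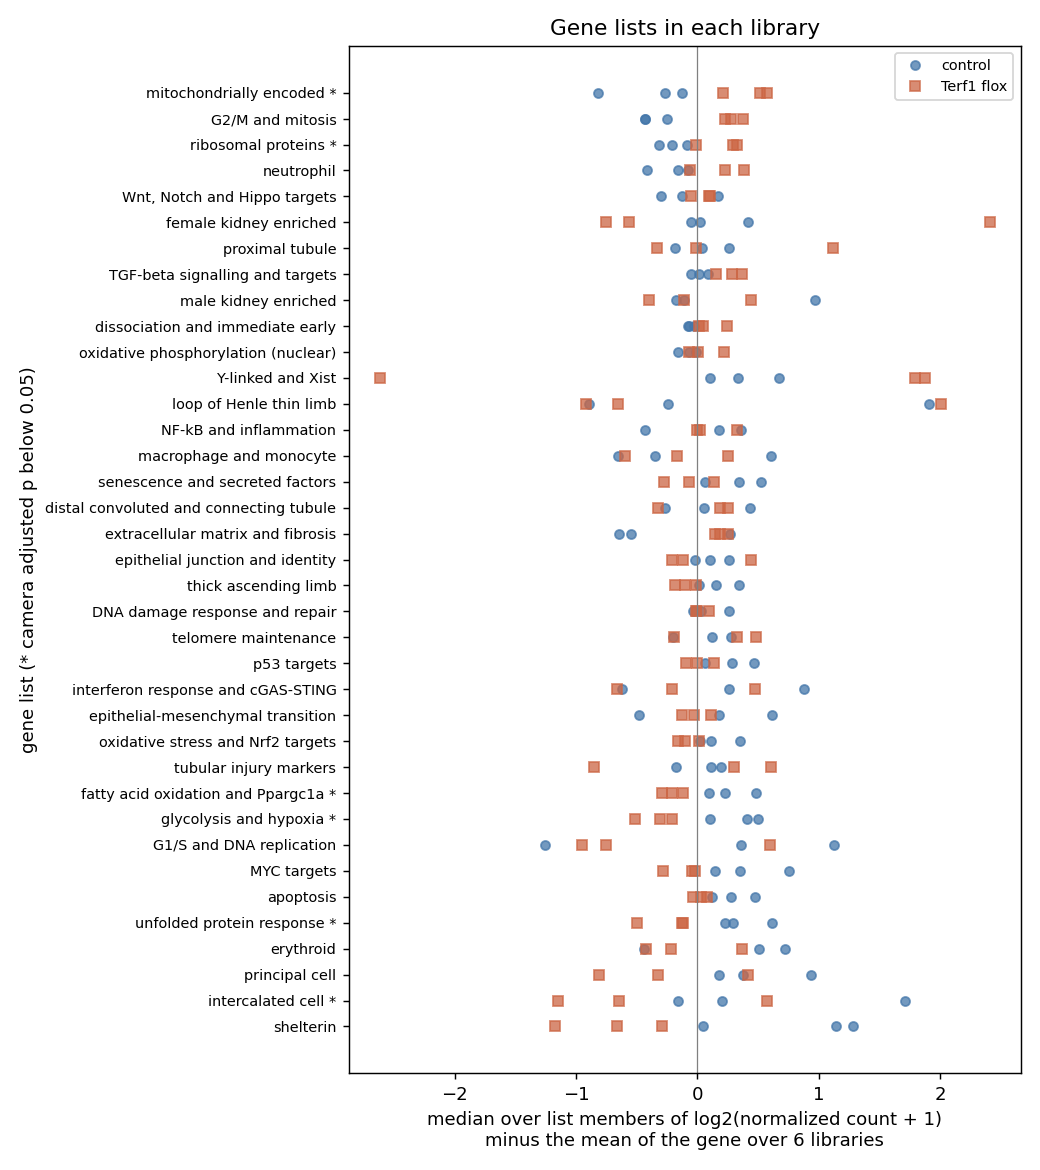
Median over the members of each tested list of the deviation of log2 (normalized count plus 1) from the mean of the gene over 6 libraries, with 1 point per library and lists ordered by median log2 fold change. Stars mark the 6 lists called by camera with the preset correlation; 0 were called with an estimated correlation.

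Nuclear genes of oxidative phosphorylation went both ways. Adjusted over the list alone, 13 of 38 were higher and 9 lower, and over all genes 0 passed in limma. The list median was 0.10 and the list was not called (camera adjusted p = 0.197). With equal totals the median was −0.07 and with quantile normalization −0.15. In leave-one-out fits it ran from 0.02 to 0.16 (camera adjusted p from 0.0539 to 0.74). The higher members included the small accessory subunits Uqcrb, Cox7b and Cox7a2 (0.98 ± 0.20). The lower ones included the catalytic subunits Sdha (−1.03 ± 0.18) and Atp5b, the ATP synthase subunit Atp5a1 (−0.87 ± 0.16) and the core subunit Uqcrc1 (−1.42 ± 0.31). With GC content and length corrected, Cox7a2 was at 0.89, Sdha at −0.63, Atp5a1 at −0.41 and Uqcrc1 at −1.45.

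Lists that describe the response to telomere damage were not called by camera, and 0 of their members passed over all genes in limma. Among p53 targets 12 of 30 were above 0 and 18 below, with a median of −0.19 (camera adjusted p = 0.984). The median was 0.15 with GC content and length corrected and ran from −0.29 to −0.01 in leave-one-out fits. Adjusted over the list alone, 0 p53 targets passed. Apaf1 (3.87 ± 1.07), Rrm2b (1.49 ± 0.51) and Bax (−3.83 ± 1.37) had the smallest limma p and pointed in different directions; with DESeq2 Apaf1 (adjusted p = 0.00593) and Bax (0.048) passed and Rrm2b did not (0.122). Bax was at −2.02 without Terf1_flox replicate 1, and Rrm2b at 0.99 with GC content and length corrected. DNA damage response and repair genes had a median of −0.16 (30 genes, adjusted p = 0.984), which was 0.09 with quantile normalization, −0.32 with equal totals, −0.41 without control replicate 3 and −0.29 without Terf1_flox replicate 1. G1/S and DNA replication genes (22 genes, adjusted p = 0.984) had a median whose sign turned with the library left out, from −0.90 without control replicate 2 to 0.41 without control replicate 3; it was also above 0 without control replicate 1 (0.06) and without Terf1_flox replicate 1 (0.34). G2/M and mitosis genes (9 of 30 tested) had a median of 0.84 (camera adjusted p = 0.298), which was 0.48 without control replicate 1 and 0.30 with a mean of at least 50. In the senescence list the lysosomal beta-galactosidase Glb1 was lower when adjusted over the list alone (441 ± 110 to 106 ± 56.2, log2 fold change −2.16 ± 0.58, limma adjusted p = 0.0499). Only 10 of the 30 senescence and secreted factor genes were tested. The list was not called (camera adjusted p = 0.942), which says nothing about the genes not tested. The shelterin list, which includes the targeted gene Terf1 itself, had a median of −1.13 (7 genes, camera adjusted p = 0.18). The median was −0.67 without control replicate 3 or without Terf1_flox replicate 3. Apart from Terf1 no member passed when adjusted over the list alone, with Pot1a at −2.34 ± 0.81 (limma adjusted p = 0.0655). In telomere maintenance the telomerase component Nop10 was higher when adjusted over the list alone (0.95 ± 0.19; list adjusted p = 0.811). Apoptosis genes had a median of −0.62 (24 genes, adjusted p = 0.755), which was −0.08 without Terf1_flox replicate 3 and −0.41 without Terf1_flox replicate 2.

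Fibrosis-related lists were not called by camera either. Extracellular matrix and fibrosis genes (14 of 34 tested) had a median of −0.05 (adjusted p = 0.669), which was 0.07 with equal upper quartiles and 0.11 with quantile normalization, against a mean of 0.18; it was also above 0 without control replicate 2 (0.55), without Terf1_flox replicate 2 (0.04) and with GC content and length corrected (0.32). Thbs1, thrombospondin 1, averaged 593 ± 288 in control and 1475 ± 128 in Terf1_flox libraries (1.45 ± 0.43, limma adjusted p = 0.202; DESeq2 adjusted p = 0.0361). Epithelial-mesenchymal transition genes (8 of 28 tested) had a median of −0.26 and a mean of 0.09 (adjusted p = 0.984); the median was 0.26 without control replicate 3 and 0.27 without Terf1_flox replicate 2. In the TGF-beta list the regulator Skil was higher when adjusted over the list alone (485 ± 43.0 to 1592 ± 363, log2 fold change 1.69 ± 0.31, limma adjusted p = 0.0117). Over all genes Skil passed with DESeq2 (adjusted p = 4.4e-05). The TGF-beta list had a median of 0.21 (25 of 30 tested, camera adjusted p = 0.495), which was 0.03 with equal totals and 0.09 without Terf1_flox replicate 2. Tubular injury markers (27 of 29 tested) had a median of −0.30 (adjusted p = 0.984), which was 0.21 without Terf1_flox replicate 1 and 0.04 with GC content and length corrected. Among them Clu, clusterin, was lower when adjusted over the list alone (7503 ± 2080 to 2257 ± 752, −1.75 ± 0.29). Clu passed over all genes in limma with equal totals, and with DESeq2 (adjusted p = 8.8e-06). Lcn2 averaged 13.7 ± 11 and 132 ± 54.4 and did not pass (3.60 ± 1.12, limma adjusted p = 0.218, DESeq2 adjusted p = 0.0588). Interferon genes (25 genes, adjusted p = 0.984) and NF-kB and inflammation genes (17 genes, adjusted p = 0.957) were not called, and the signs of their medians turned with the scaling and with the library left out.

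Among nephron segments, thick ascending limb markers had a median of −0.07 (14 genes, camera adjusted p = 0.365), which was 0.05 with equal upper quartiles; with quantile normalization it was −0.25 and the list was called (adjusted p = 0.0125). The median was also above 0 without Terf1_flox replicate 2 (0.01) and with GC content and length corrected (0.16). Adjusted over the list alone, Umod (−0.90 ± 0.15), Ptger3 (−1.33 ± 0.33) and Kcnj1 (−0.90 ± 0.26) were among the lower members and Slc12a1 was higher (0.47 ± 0.13), at 0.30 with equal totals and 0.06 with quantile normalization. Umod passed over all genes in limma with equal totals, and with DESeq2 (adjusted p = 0.00139). The log2 fold change of Umod was −0.31 after GC content and length correction (limma adjusted p = 0.301). Proximal tubule markers had a median of 0.23 (23 genes, adjusted p = 0.544; −0.10 without Terf1_flox replicate 3), with the brush border enzyme Ggt1 lower when adjusted over the list alone (−2.40 ± 0.49). Distal convoluted and connecting tubule markers (15 genes, adjusted p = 0.984) were not called, and principal cell markers had a median of −1.0 (13 genes, adjusted p = 0.422), which was −0.48 without Terf1_flox replicate 2 and −0.33 with GC content and length corrected.

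The first 3 principal components held 25.7%, 23.8% and 20.6% of the variance. The control libraries lay at −25.4, −28.6 and −57.3 on the first and the Terf1_flox libraries at 18.1, 86.1 and 7.18. On the second component Terf1_flox replicate 3 stood apart at 94.1, with the others between −34.6 and 7.85. In that library the median deviation of female-enriched kidney genes was 2.41, against −0.75 to 0.41 in the others. Its proximal tubule markers had a median deviation of 1.12, against −0.33 to 0.26. Whether sex or cell make-up sets this library apart was not tested.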

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

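The GC content and length correction and the count of genes at an unadjusted p below 0.05 were added after the data were seen. Relative to the deposited scaling, the median of all genes shifted by −0.17 (log2) with equal totals, 0.12 with equal upper quartiles and 0.15 with quantile normalization. The limma count of 0 called genes became 132 with a mean of at least 50 (40 higher, 92 lower), 45 with equal totals (1 higher, 44 lower), 8 with quantile normalization and 772 with DESeq2; the cause was not tested. It stayed 0 under the other 11 alternatives and without each library, with 1487 to 2060 genes at an unadjusted p below 0.05 when a library was left out and 1744 to 2360 elsewhere.

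Terf1 kept its direction throughout, from −4.17 to −3.82 (limma, edgeR or DESeq2 adjusted p from 5.42e-08 to 0.236), and from −4.42 to −3.77 in leave-one-out fits (0.159 to 0.332). It passed with a mean of at least 50 (−3.99, 0.0285), with equal totals (−4.17, 0.0497) and with DESeq2 (−3.89, 5.42e-08). The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated from −0.049 to 0.00013 across genes. With the replicate block, 0 genes were called, 1884 had an unadjusted p below 0.05, 6 lists were called and Terf1 was at −3.99 (limma adjusted p = 0.236). With Xist as a covariate 0 genes were called and the adjusted p of Terf1 was 0.147.

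The 6 called lists became 3 after GC content and length correction, 0 with an estimated correlation and 0 with fry, tests that leave the medians as they were; 4 to 6 were called in leave-one-out fits (4 without control replicate 3). With both of these tests the medians were 0.93 for mitochondrially encoded, 0.45 for ribosomal protein, −0.42 for glycolysis and hypoxia, −0.73 for unfolded protein response, −0.41 for fatty acid oxidation and −1.04 for intercalated cell genes. The correction ended the calls of mitochondrially encoded (0.22), fatty acid oxidation (−0.33) and intercalated cell genes (−0.58), and array weights that of intercalated cell genes (−0.92). In leave-one-out fits the unfolded protein response median ran from −0.95 to −0.62, the intercalated cell median from −1.34 to −0.44, the glycolysis and hypoxia median from −0.81 to −0.36 and the mitochondrially encoded median from 0.59 to 1.00, the latter pair called throughout. The first principal component held 27.3% with 500 genes and 26.3% with all genes. Of the named-gene values under alternatives, 3102 kept their side of the threshold, 135 passed it in the same direction and 0 went past it the other way. Signs of values short of the threshold did turn for some genes, such as Eif2s3y (−1.71 to 1.29, and −3.04 to 1.85 in leave-one-out fits) and Ddx3y (−1.51 to 0.83). At this spread and n, changes of 2-fold were seldom recovered in simulated reads (2% by limma).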

Other observations

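MYC target genes, many of them ribosome biogenesis factors and chaperones, had a median log2 fold change of −0.55 (21 of 29 below 0; camera adjusted p = 0.298), which was −0.17 without Terf1_flox replicate 2. Adjusted over the list alone, the chaperonin subunits Cct3 (−1.79 ± 0.37) and Hspd1 (−2.03 ± 0.45) and the nucleolar protein Nop56 (−4.58 ± 1.10) were lower. Of the oxidative stress and Nrf2 target genes (23 genes, adjusted p = 0.495), sulfiredoxin Srxn1 (−1.75 ± 0.39) and Pgd (−2.53 ± 0.63) were lower and peroxiredoxin Prdx1 was higher (0.71 ± 0.17; 0.21 with GC content and length corrected) when adjusted over the list alone. Among Wnt, Notch and Hippo targets (17 genes, adjusted p = 0.811), cyclin D1 (Ccnd1) averaged 2240 ± 374 in control and 669 ± 145 in Terf1_flox libraries and was lower when adjusted over the list alone (−1.75 ± 0.29). Ccnd1 passed over all genes in limma with equal totals, and with DESeq2 (adjusted p = 1.04e-05). Immediate early and dissociation genes were not called (25 genes, adjusted p = 0.984), with Ier2 lower when adjusted over the list alone (−2.81 ± 0.61). Epithelial junction and identity genes were not called (27 genes, adjusted p = 0.984). Over all genes, 0 of these members passed in limma with the deposited scaling and a mean of at least 10.

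Camera did not call the markers of the thin limb of Henle (9 genes, adjusted p = 0.984), macrophages and monocytes (10 genes, adjusted p = 0.984), neutrophils (3 genes, adjusted p = 0.669) or erythroid cells (6 genes, adjusted p = 0.755). Among these, Ltf ran from 378.1 to 914.9 and Bpgm from 264.3 to 1030.9 normalized counts over the libraries. Male-enriched (7 genes, adjusted p = 0.984) and female-enriched kidney genes (12 genes, adjusted p = 0.811) were not called either. The Y-linked gene Eif2s3y held 394, 512 and 478 normalized counts in control and 1777, 1538 and 1.01 in Terf1_flox libraries, and Ddx3y held 347, 123 and 611 and 915, 951 and 3.04. Xist, expressed from the inactive X chromosome of females, held 1911, 2872 and 1380 in control and 1577, 2241 and 2700 in Terf1_flox libraries. Terf1_flox replicate 3 thus held few Y-linked reads, with Kdm5d at 12.1 and Uty at 16.2 (26.0 in control replicate 3). The libraries other than Terf1_flox replicate 3 held both Y-linked and Xist reads. The labels give no sex per library and do not say whether a library is 1 mouse or a pool. The Y-linked and Xist list was not called (6 genes, adjusted p = 0.984), and without Terf1_flox replicate 3 its median was 1.44 and it was called (adjusted p = 0.0263).

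The tests of loss of cytoplasmic RNA, of a single library behind the intercalated cell markers and of transcript length in oxidative phosphorylation genes, and the GC content and length correction itself, were chosen after those results were seen. So were the comparisons of gene counts, by limma and by DESeq2, over other splits of the libraries. Limits on chance are set by the design: 6 libraries split into 3 and 3 in only 10 ways, too few for a share under 0.05. limma called 0 genes in the real split, so 10 of 10 splits must give as many whatever the data, and that count says nothing about chance; the highest other was also 0. At an unadjusted limma p below 0.05, the real split gave 2095 genes and the highest other 750, so 1 of 10 splits reached it; DESeq2 gave 772 and 74, again 1 of 10. Camera called 6 lists in the real split and 6 in the highest other, and 3 of 10 splits gave as many. With an estimated correlation 0 lists were called in any split, so that count says nothing about chance either.

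The 5 called process and technical lists were weighed against a GC content and length bias between libraries, fitted on all genes outside each list and removed. The mitochondrially encoded median moved from 0.93 to 0.20 (camera adjusted p = 0.56), so such a bias may account for that list, whose transcripts have a median GC content of 37.1%. Loss of cytoplasmic RNA from damaged cells was weighed by the nuclear RNAs Malat1, Neat1, Xist and Kcnq1ot1. Their median was 0.16 (Malat1 0.10 ± 0.12, though Neat1 0.51 ± 0.29). Ribosomal protein genes, which such a loss would lower, had a median of 0.45. These values argue against such a loss as the source of the full uncorrected rise of 0.93. They cannot decide about the 0.20 left after the correction, which is near the nuclear median. Xist also depends on the sex make-up, which is not given. The ribosomal protein median went from 0.45 to 0.53 (camera adjusted p = 2.67e-09) and the glycolysis and hypoxia median from −0.42 to −0.24 (camera adjusted p = 0.00849). The unfolded protein response median went from −0.73 to −0.61 (camera adjusted p = 0.00827). Removing the trend thus left these 3 calls in place under the preset correlation. With an estimated correlation their adjusted p after correction were 0.813, 0.808 and 0.807. The trend rests on medians over annotated transcripts, which may differ from the expressed ones, so a remaining bias cannot be excluded. For fatty acid oxidation (−0.41 to −0.33, quartiles from −1.05 to −0.00353 before and from −0.81 to 0.01 after, adjusted p = 0.0906) the bias and the genotype cannot be told apart, because the median moved little while the call ended. The GC trend itself follows the genotype in all 6 libraries, so an effect of Trf1 loss on these lists stays open, as untested.

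The lower intercalated cell markers could reflect the cell make-up of control replicate 3 alone, in which the transcription factor Foxi1 stood at 1668 normalized counts, against 0 to 240.2 in the other libraries. Without that library the median was −0.44 in place of −1.04 (adjusted p = 0.448). Terf1_flox replicate 1, with a median deviation of 0.57, lay above control replicates 1 and 2 (−0.16 and 0.20). The call also ended without Terf1_flox replicate 3 (−0.56, adjusted p = 0.32) and without Terf1_flox replicate 2 (−0.72, adjusted p = 0.0645), so a single library and a difference between the groups cannot be told apart with 3 libraries each. A lower share of intercalated cells in Terf1_flox sorts stays open, as untested.

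The oxidative phosphorylation genes that were higher had mostly short annotated transcripts. Across the 38 genes the Spearman correlation of log2 fold change with transcript length was −0.54 (permutation p = 0.00045), and after GC content and length correction −0.35 (permutation p = 0.03); genes are not independent replicates. Over all 14489 genes with transcript values, the Spearman correlation of log2 fold change with length was −0.0025. The median log2 fold change was 0.15 in the shortest of 5 length bins, −0.22, −0.27 and −0.12 in the next bins and 0.07 in the longest. As the relation within the list outlasted the correction, it does not show whether a length bias accounts for part of this split. By these lengths Uqcrc1 (533 nt) and Ndufs1 (651 nt), at −1.42 and −0.62, and Cycs (3123 nt), at 0.74, went against the relation. Each length is a median over annotated transcripts and may not be that of the expressed one, so these few genes cannot decide. An effect of genotype on the oxidative phosphorylation genes stays open, as untested.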
